A study of Mus musculus with 10 samples.

How the data were processed

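RNA of 10 mouse samples, isolated with TRIzol and cleaned on columns per the labels, was biotin-labelled and hybridised to arrays by the Affymetrix protocol. The deposited log2 values, 1 table of 41345 transcript clusters by 10 arrays, were used as the authors made them. The submitters' processing notes name RMA, oligo 1.38.0, R 3.3.1 and Transcriptome Analysis Console without saying what each was used for. The summarisation level of RMA and the genome build are not given in the sources used here. That the values are log2 was read from their range, since they ran from 1.27 to 13.58 with array medians of 4.91 to 5.07. Scanner files were not used here, so background correction could not be repeated and no probe could be tested against its background.

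Groups were taken from the cell type in the labels: 4 arrays of embryonic stem cells, 3 of hepatocyte-like cells and 3 of adult hepatocytes. The annotation of the platform gave 1 gene symbol for 23521 clusters, several for 1814 and none for 16010. No gene was named from a cluster with several symbols. Entrez identifiers of 23328 of the clusters with 1 symbol were found in the RefSeq annotation of GRCm38.p6, and 0 symbols had changed. Where a gene had more than 1 cluster (1082 genes), the one with the highest mean over all 10 arrays was kept, which left 22180 genes.

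Each of the 3 comparisons was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on the log2 values, in 1 fit of all 10 arrays with group means and no other term, which leaves 7 residual degrees of freedom beside a prior of 5.34. P-values were adjusted by the Benjamini-Hochberg method over all 22180 genes. A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 either way, and the words rose and fell are used for called genes. Differences are given with their standard error from the fit.

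The 28 gene lists covered NKG2D ligands, other activating or adhesion ligands of natural killer cells, inhibitory ligands, MHC class I presentation, interferon-stimulated genes, the killing pathway with granzyme inhibitors, the p53 and DNA damage response, naive pluripotency, primed epiblast, mesendoderm and definitive endoderm, fetal liver and hepatoblast, hepatocyte transcription factors, plasma proteins, metabolic enzymes, cytochrome P450 and conjugation, Kupffer cells and macrophages, endothelium, stellate cells and fibroblasts, cholangiocytes, lymphocytes, erythroid cells, extraembryonic endoderm, trophoblast, cardiac and muscle, neural, proliferation, early response to dissociation, and sex chromosome genes. They held 496 different genes, of which 441 were measured, and some genes stand in more than 1 list. Lists were tested with camera at its preset correlation of 0.01 and again with the correlation estimated per list, and with fry as an alternative, each adjusted over the 28 lists. A p-value for a list is camera's at the preset correlation unless another is named.

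The groups, tests, thresholds, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule takes, per comparison, the 6 called genes with the largest differences each way whose groups do not overlap, without clone names, predicted models, small RNAs or pseudogenes, every measured NKG2D ligand, any MHC class I gene, and from the other lists up to 4 members in order of the size of their difference, or for other cell types also by level.

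The scripts were tested on simulated data. For hepatocyte-like against embryonic stem cells, 78% of 100 genes shifted by 1.5 and 100% of 100 shifted by 3 were called among 22180, with 6 false calls. For adult hepatocytes against embryonic stem cells these were 82%, 99% and 7, and for hepatocyte-like cells against adult hepatocytes 75%, 100% and 4. In a simulation with 1 shifted list, 1 of 28 lists was called with the preset correlation, the shifted one. That list was also called with an estimated correlation. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. A simulated set of 200 genes of which 50% were shared gave 50%.

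The alternatives were quantile normalization again, centring on the median, cyclic loess, leaving out dim genes, the mean over a gene's clusters, a trended and robust variance, array weights, only the 2 groups compared, the replicate number as a block, each array left out in turn, every cluster, other thresholds and other list tests. Subtracting adult transcripts from hepatocyte-like replicate 3 was added later. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.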

Results

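Transcript levels were measured on 10 arrays of mouse cells: 4 arrays of embryonic stem cells, 3 of hepatocyte-like cells, which had been differentiated from embryonic stem cells, and 3 of hepatocytes from adult liver. All 10 samples carry the same strain label, that of a mouse line with luciferase and green fluorescent protein under the CAG promoter. From the transcript clusters of the arrays 22180 genes were tested. The median log2 level of an array lay between 4.91 and 5.07, and the number of arrays limits the precision. The series title concerns NKG2D, an activating receptor of natural killer cells, and its part in the response to hepatic cells made from stem cells. The comparisons below therefore cover both the hepatic state of the cells and the ligands that natural killer cells read.

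Arrays of one kind resembled each other more than those of any other kind. Across all transcript clusters of the table, Pearson's r was 0.960 to 0.978 among adult hepatocytes, 0.963 to 0.976 among hepatocyte-like cells and 0.968 to 0.985 among embryonic stem cells. Between kinds it was 0.905 to 0.927 for hepatocyte-like cells with embryonic stem cells, 0.833 to 0.849 for hepatocyte-like cells with adult hepatocytes and 0.817 to 0.832 for adult hepatocytes with embryonic stem cells. These correlations run across clusters within pairs of arrays, and clusters are not independent replicates.

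The first comparison set hepatocyte-like cells (n = 3) against embryonic stem cells (n = 4) and asks what differentiation changed. Genes of the naive pluripotency network were far lower in hepatocyte-like cells: 25 of 28 measured members fell and 0 rose (camera, adjusted p = 9.56e-26). Nr0b1 fell by 6.95 ± 0.18 (log2 difference ± SE), Fbxo15 by 6.64 ± 0.19, the transcription factor Nanog fell by 6.44 ± 0.40 and the Nodal co-receptor Tdgf1 fell by 6.28 ± 0.53. Fetal liver and hepatoblast genes moved the other way, with 12 of 19 higher and 0 lower (adjusted p = 3.27e-07). The epithelial keratins Krt18 and Krt8 rose by 5.10 ± 0.34 and 4.09 ± 0.30, the growth factor Igf2 by 4.64 ± 0.23 and the imprinted gene Peg3 by 4.20 ± 0.19. Extraembryonic endoderm genes also rose, 11 of 18 with 0 lower (adjusted p = 5.13e-09). They included the basement membrane genes Col4a1 (4.60 ± 0.26), Col4a2 (4.18 ± 0.27) and Lamb1 (3.95 ± 0.21) and the endoderm transcription factor Gata6 (4.22 ± 0.35). In all, 3540 genes were called, 1909 higher and 1631 lower, but with each array centred on its median 1705 were higher and 1848 lower.

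Genes typical of stellate cells and fibroblasts were among the strongest in hepatocyte-like cells. Of 20 measured, 14 rose and 0 fell (adjusted p = 1.55e-11), although not as a group when the correlation was estimated (adjusted p = 0.157 with an estimated correlation). The matrix gene Postn rose by 6.88 ± 0.38, smooth muscle actin Acta2 by 6.32 ± 0.24, the collagen Col1a1 by 5.21 ± 0.50 and the collagen cross-linking enzyme Lox by 4.55 ± 0.27. Beside Postn and Acta2, the largest rises in named genes were those of Nrk (6.92 ± 0.21), the prostaglandin synthase Ptgs2 (6.67 ± 0.26), the matrix genes Thbs1 (6.54 ± 0.31) and Tnc (6.07 ± 0.58). The largest falls beside the pluripotency genes were those of the zinc finger genes Zfp981 (-6.56 ± 0.44) and Zfp640 (-6.53 ± 0.45), members of a family with near-identical copies, so that 1 probe can read several of them. Of 8 cholangiocyte genes 3 rose and 0 fell (adjusted p = 0.0260, and adjusted p = 0.465 with an estimated correlation), led by Krt19 (4.06 ± 0.27) and Sox9 (2.82 ± 0.47). With dim genes left out that list was not called (adjusted p = 0.143).

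Mature hepatocyte functions changed little between embryonic stem cells and hepatocyte-like cells. Of 31 cytochrome P450 and conjugation genes 0 rose and 2 fell, Gstp1 by 3.31 ± 0.32 and the oxidase Aox3 by 3.08 ± 0.27 (list adjusted p = 0.947). Of 27 metabolic enzymes 1 rose, the glutamine synthetase Glul (1.44 ± 0.26), and 3 fell, Cpt1a (-2.55 ± 0.18), Aldh2 (-2.33 ± 0.24) and Adh1 (-1.61 ± 0.32; list adjusted p = 0.920). Among 21 hepatocyte transcription factors 4 rose, including Zhx2 (1.88 ± 0.17), Foxa1 (1.67 ± 0.47) and Prox1 (1.52 ± 0.32), and Nr5a2, which also acts in pluripotent cells, fell by 4.05 ± 0.19 (list adjusted p = 0.240). Foxa1 was not called without hepatocyte-like replicate 2, at 0.94 (adjusted p = 0.0431), and Glul and Adh1 were not called when a gene's clusters were averaged, at 0.62 and -0.91. For the conjugation and metabolic lists the median (0.14 and 0.11) and the test pointed up and the mean (-0.10 and -0.05) down. Plasma protein genes were mixed, with 7 of 30 higher and 2 lower. Fibrinogen chain Fgb rose by 3.18 ± 0.27, transthyretin Ttr by 3.10 ± 0.32 and apolipoprotein Apob by 3.05 ± 0.48, while Fetub fell by 3.49 ± 0.24. This list was called at adjusted p = 0.00634, but not with the correlation estimated (adjusted p = 0.581 with an estimated correlation) nor without hepatocyte-like replicate 3 (adjusted p = 0.231, in a range of 3.80e-04 to 0.231 over the alternatives that keep the preset correlation).

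Hepatocyte-like replicate 3 stood apart from replicates 1 and 2 in the most abundant adult hepatocyte transcripts. The mean level of the plasma protein list was 6.28 in replicate 3 against 5.27 and 5.49, and that of albumin, Alb, was 10.80 against 4.85 and 5.14, so that Alb did not pass the test against embryonic stem cells (2.03 ± 1.05, adjusted p = 0.189). It passed without replicate 1 (3.07, adjusted p = 0.0473), and its difference was 0.10 without replicate 3. Of 34 genes that were abundant in adult hepatocytes and at the floor on the 4 arrays of embryonic stem cells, 34 lay above all 4 in replicate 3, against 12 and 14 in replicates 1 and 2. Their median excess over the stem cell mean was 1.24 in replicate 3 (quartiles 0.81 and 1.98), 0.07 in replicate 1 and 0.09 in replicate 2. Among such genes at adult levels of 8 to 9, replicate 3 had fewer above the stem cells, 59 of 125 against 76 and 78. Alpha-fetoprotein, Afp, an early hepatic transcript, was lower in replicate 3 at 6.69 than in replicates 1 and 2 at 9.13 and 9.30. Replicate 3 also stood apart in genes that adult hepatocytes do not carry: Nanog was at 7.12 against 5.08 and 5.09, Tdgf1 at 6.50 against 3.90 and 3.83 and the placental gene Esx1 at 8.51 against 5.28 and 5.25. Col1a1 was lower there, at 9.80 against 12.80 and 11.92. These genes, Alb, Afp and the abundant adult genes were singled out after their values were seen.

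**Figure D1:**
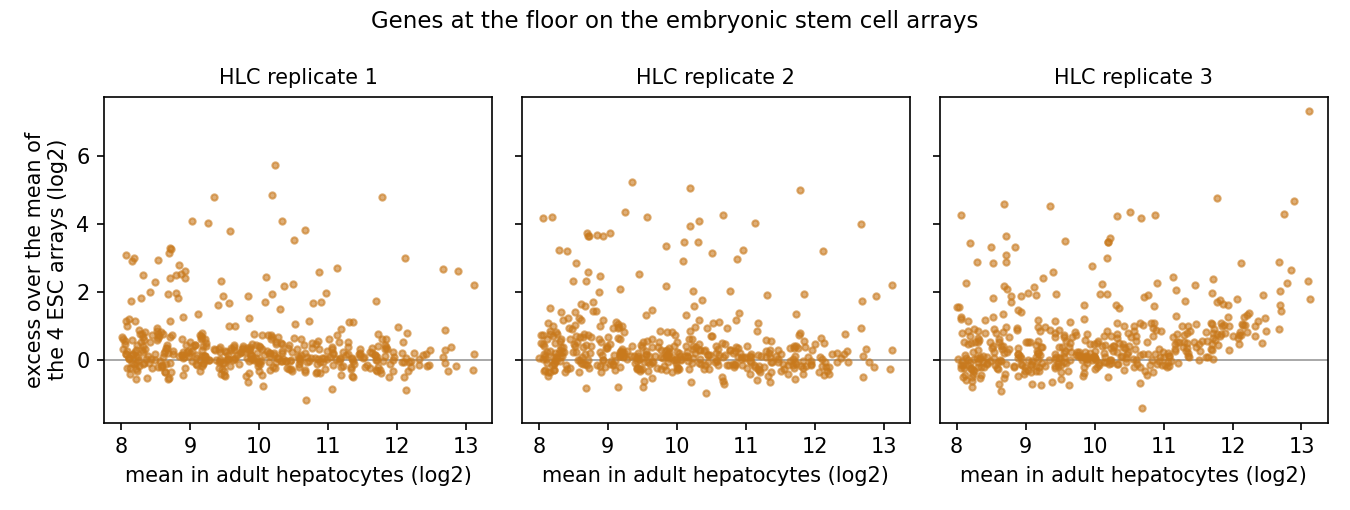
Excess of single genes in each hepatocyte-like (HLC) array over the mean of the 4 arrays of embryonic stem cells (ESC; y axis, log2), against the mean level in adult hepatocytes (x axis, log2), for the same genes in each panel. Each point is a gene below 5.5 on all 4 stem cell arrays and at least 8 in adult hepatocytes, and above an adult level of 12 the median excess was 1.24 in replicate 3 against 0.07 and 0.09 in replicates 1 and 2.

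Cell division genes were lower in hepatocyte-like cells, with 13 of 21 falling and 0 rising (adjusted p = 4.73e-07, and adjusted p = 0.581 with an estimated correlation). The replication licensing genes led: Mcm5 fell by 2.87 ± 0.33, Mcm3 fell by 2.45 ± 0.36 and Mcm2 fell by 2.16 ± 0.28. The mean level of this list was 7.36 in hepatocyte-like replicate 2 against 8.90 and 8.78 in replicates 1 and 3. Genes that respond early to dissociation rose in 8 of 18 and fell in 2, with Fos at 2.43 ± 0.33, Jun at 2.39 ± 0.27, Egr1 at 2.32 ± 0.50 and Ier3 at 2.05 ± 0.20 (adjusted p = 0.0394). That list call was lost with the correlation estimated (adjusted p = 0.581 with an estimated correlation), without hepatocyte-like replicate 3 (adjusted p = 0.205), without embryonic stem cell replicate 1 (adjusted p = 0.0975), with dim genes left out (adjusted p = 0.102) and with array weights (adjusted p = 0.0910). With the preset correlation its range over the alternatives was 0.00946 to 0.205. Among p53 and DNA damage response genes 6 of 19 rose, including Plk2 (2.11 ± 0.19), Eda2r (1.80 ± 0.18) and Btg2 (1.62 ± 0.31), and 3 fell, led by the checkpoint kinase Chek2 (-2.53 ± 0.18; list adjusted p = 0.240).

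Markers of further lineages moved as single genes, and none of the following lists was called. Among primed epiblast genes 2 of 11 rose and 3 fell (adjusted p = 0.947), with Cldn6 at 3.94 ± 0.25 and Dnmt3b at -2.38 ± 0.41. Among mesendoderm and definitive endoderm genes 5 of 17 rose and 2 fell (adjusted p = 0.130), the latter being Trh (-4.33 ± 0.44) and Kit (-3.17 ± 0.23). Of 9 trophoblast genes 3 rose, Hand1 (2.37 ± 0.46), Plac1 (2.20 ± 0.55) and Krt7 (1.79 ± 0.34), and Tfap2c fell by 1.61 ± 0.43 (adjusted p = 0.254). Plac1 was at 1.23 without hepatocyte-like replicate 3, and Tfap2c was not called without hepatocyte-like replicate 1 (-1.27, adjusted p = 0.0575). Endothelial genes were split, 2 of 14 each way (adjusted p = 0.783), with the receptor Kdr up by 2.63 ± 0.24 and Pecam1 at -3.07 ± 0.19. Neural genes were split as well, 2 of 13 each way (adjusted p = 0.947), as were macrophage genes, 1 of 16 each way (adjusted p = 0.947), and interferon-stimulated genes, 3 of 21 each way (adjusted p = 0.783). Cardiac and muscle genes rose in 2 of 14 (adjusted p = 0.592), lymphocyte genes fell in 3 of 11 (adjusted p = 0.111, and 0.0262 without hepatocyte-like replicate 2), and 0 of 6 erythroid and 0 of 4 sex chromosome genes were called (adjusted p = 0.866 and 0.651). Counts adjusted over the list alone were the same for each of the 28 lists except fetal liver (13 higher and 1 lower), extraembryonic endoderm (12 higher) and cell division (16 lower).

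In total 9 of 28 lists were called with camera's preset correlation and 3 with an estimated one, namely naive pluripotency (adjusted p = 0.00809), fetal liver (adjusted p = 0.00809) and extraembryonic endoderm (adjusted p = 0.0149). Other splits of the same 7 arrays gave up to 13 lists with the preset correlation and 0 with an estimated one. Nothing in the labels says whether the numbered replicates came from separate cultures or animals beyond calling them biological, so the p-values measure the spread between these samples.

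**Figure D2:**
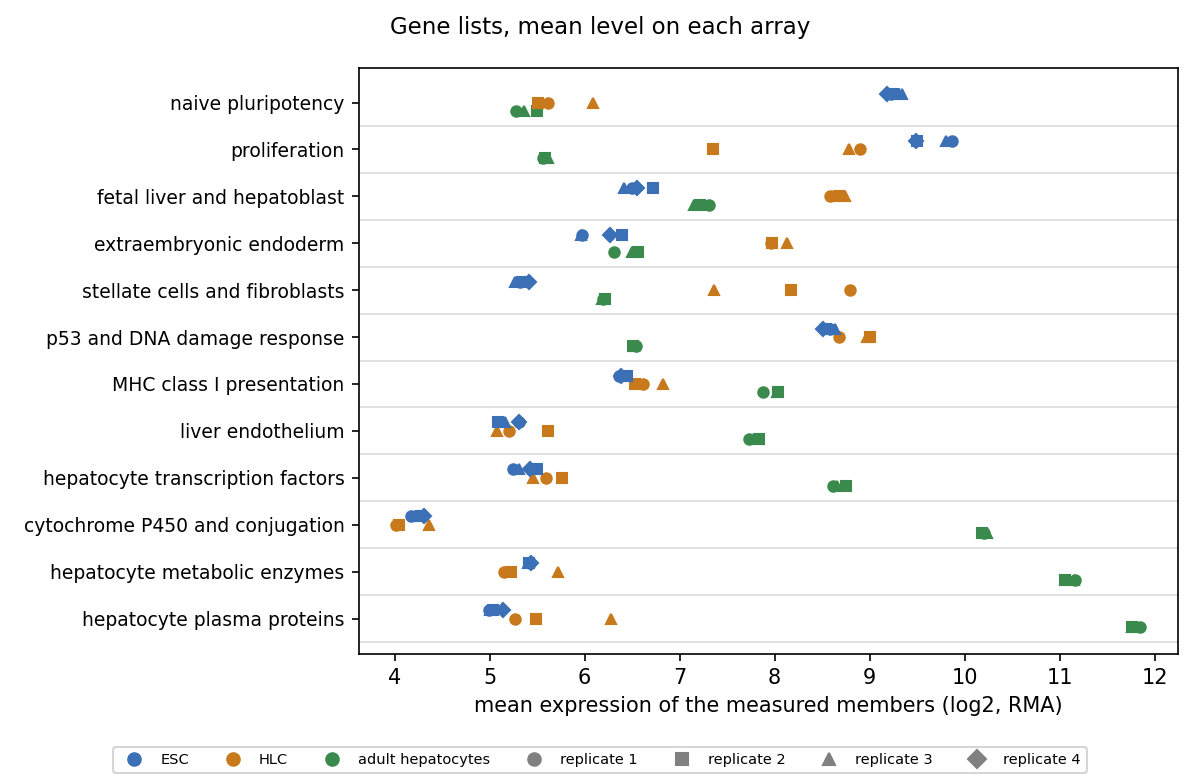
Mean log2 level of the measured members of 12 gene lists (x axis) on each of the 10 arrays, for embryonic stem cells (ESC, blue), hepatocyte-like cells (HLC, orange) and adult hepatocytes (green), with the marker shape giving the replicate. Hepatocyte-like cells lay far below embryonic stem cells for naive pluripotency (group means 5.74 and 9.25), above both other groups for fetal liver genes (8.67 against 6.55 and 7.22), and near embryonic stem cells for the 4 mature hepatocyte lists.

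Ligands of NKG2D were then compared. Of 9 listed ligands 3 could be measured singly, H60b, H60c and Ulbp1, and the others were not analysed here as single genes because the annotation puts them on a cluster with several symbols or does not list them. In hepatocyte-like cells (n = 3) H60b stood at 6.90 ± 1.57 (mean log2 ± SD), against 4.76 ± 0.76 in embryonic stem cells (n = 4) and 4.01 ± 0.50 in adult hepatocytes (n = 3). It rose by 2.14 ± 0.60 (SE) over embryonic stem cells, a 4.41-fold difference (adjusted p = 0.0158), and by 2.90 ± 0.64 over adult hepatocytes, 7.45-fold (adjusted p = 0.00287). The single arrays read 8.05, 5.12 and 7.54, so replicate 2 lay within the range of the stem cells, and the call against embryonic stem cells was lost without hepatocyte-like replicate 1 (1.57, adjusted p = 0.0759) and without replicate 3 (1.82, adjusted p = 0.0667). Over the alternatives the adjusted p of H60b in that comparison ranged from 2.69e-04 to 0.0759. Ulbp1 was high in both cultured kinds, at 6.72 ± 0.58 in hepatocyte-like cells and 6.19 ± 0.27 in embryonic stem cells, and low in adult hepatocytes at 4.52 ± 0.33. It was higher in hepatocyte-like cells than in adult hepatocytes by 2.19 ± 0.28 (adjusted p = 4.01e-05) and lower in adult hepatocytes than in embryonic stem cells (-1.67 ± 0.26, adjusted p = 1.65e-04). It did not pass the test between hepatocyte-like and embryonic stem cells, with a difference of 0.52 ± 0.26 (adjusted p = 0.173, 95% interval -0.05 to 1.09). H60c stood at 4.85, 4.74 and 4.91 in hepatocyte-like cells, embryonic stem cells and adult hepatocytes, and its largest difference, adult hepatocytes against embryonic stem cells, was 0.17 ± 0.15 (adjusted p = 0.407, 95% interval -0.15 to 0.48). These means lay below 5.5, the level taken as the floor here. So did those of H60b in both other kinds, Ulbp1 in adult hepatocytes and the Raet1 cluster in stem cells. Folds against such levels are uncertain, and the interval of H60c gives no bound on a low transcript. Adjusted over the list alone, 1 ligand was called in hepatocyte-like against embryonic stem cells, 1 in adult hepatocytes against embryonic stem cells and 2 in hepatocyte-like cells against adult hepatocytes, the same counts as over all genes. These counts leave out the cluster shared by Raet1 genes. In limma over all clusters it was higher in hepatocyte-like than in embryonic stem cells by 1.19 ± 0.22 (adjusted p = 0.00255). The list as a whole was not called in any of the 3 comparisons (adjusted p = 0.302, 0.521 and 0.161), while fry, which does not compare a list with other genes, gave an adjusted p = 0.0397, 0.0394 and 0.00123.

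**Figure D3:**
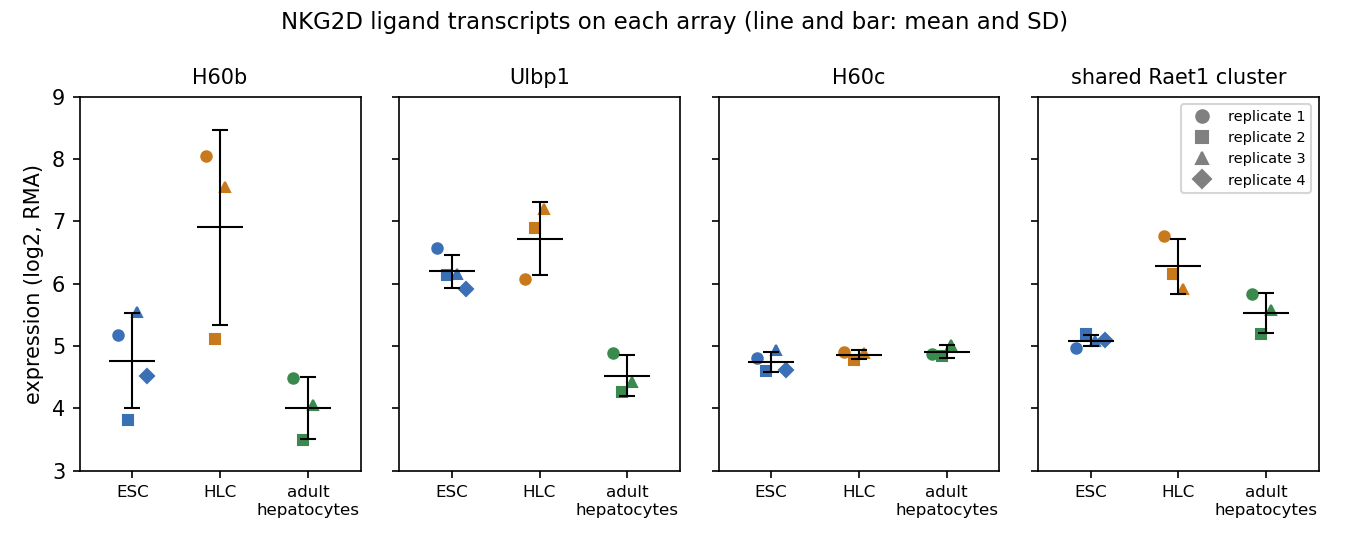
Log2 level (y axis) of 3 NKG2D ligands and of a transcript cluster shared by Raet1 genes on each array, with the replicate as marker shape and the mean and SD as line and bar, for embryonic stem cells (ESC, n = 4), hepatocyte-like cells (HLC, n = 3) and adult hepatocytes (n = 3). H60b spans 5.12 to 8.05 in hepatocyte-like cells, and Ulbp1 is at most 4.89 on the adult arrays and at least 5.92 on the others.

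Other ligands and target-cell genes of the natural killer response changed singly in hepatocyte-like cells relative to embryonic stem cells. Of 12 inhibitory ligands 4 rose and 2 fell (list adjusted p = 0.194). The phagocytosis checkpoint Cd47 rose by 3.91 ± 0.15, the cadherin Cdh2 by 3.70 ± 0.23 and the galectin Lgals9 by 1.35 ± 0.28, while Cdh4 fell by 1.46 ± 0.20. Lgals9 was not called without hepatocyte-like replicate 2 (0.95), nor Cdh4 with its clusters averaged (-0.75). Of 16 other activating or adhesion ligands 2 rose, Cd24a (2.43 ± 0.35) and Ncam1 (2.20 ± 0.23), and the adhesion molecule Icam1 fell by 1.46 ± 0.28 (list adjusted p = 0.451). That list mixes adhesion molecules with activating ligands, so in any comparison a change of Cd24a or Ncam1 is no measure of activation. In the MHC class I pathway 4 of 17 genes rose and 0 fell, a list not called (adjusted p = 0.525). They were B2m (1.64 ± 0.23), H2-K1 (1.34 ± 0.29), the trimming peptidase Erap1 (1.19 ± 0.32) and the peptide transporter Tap1 (1.05 ± 0.24). Erap1 was not called without hepatocyte-like replicate 3 (0.83, adjusted p = 0.0581), and Tap1 fell short of a log2 difference of 1 without hepatocyte-like replicate 2 (0.76), without embryonic stem cell replicate 1 (0.93) and with arrays centred on their median (0.97). Genes of the killing pathway and granzyme inhibitors rose in 9 of 18 and fell in 1 (adjusted p = 0.00129, and adjusted p = 0.0953 with an estimated correlation). The serpins Serpina3n and Serpinb9, the latter an inhibitor of granzyme B, rose by 4.83 ± 0.23 and 2.50 ± 0.31, the death receptor Fas by 3.53 ± 0.26 and its caspase Casp8 by 2.35 ± 0.27.

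The second comparison set adult hepatocytes (n = 3) against embryonic stem cells (n = 4) and gives the whole difference between these samples. That includes parts not particular to hepatocytes, such as cell division genes and markers of other liver cells. Adult hepatocytes had all 30 measured plasma protein genes higher (adjusted p = 4.75e-27), with Serpina1c up by 8.93 ± 0.83, the fibrinogen chains Fgb and Fgg by 8.67 ± 0.27 and 8.64 ± 0.24 and Alb by 8.54 ± 1.05. Standard errors come from the fit of all 3 groups. The spread between the hepatocyte-like arrays therefore widens those of Serpina1c and Alb here and of Hamp below. Of 31 cytochrome P450 and conjugation genes 29 rose (adjusted p = 4.95e-27), led by Cyp2j5 (8.53 ± 0.25) and the carboxylesterase Ces3a (8.46 ± 0.15). Of 27 metabolic enzymes 25 rose (adjusted p = 6.69e-24), including the bile acid synthesis enzyme Cyp7a1 (7.89 ± 0.19) and the organic anion transporter Slco1b2 (8.53 ± 0.31). Of 21 hepatocyte transcription factors 19 rose (adjusted p = 1.24e-14), among them Prox1 (5.56 ± 0.32), Cebpa (5.05 ± 0.23) and the bile acid receptor Nr1h4 (4.98 ± 0.16). Altogether 5893 genes were called, 2443 higher and 3450 lower.

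Beside Serpina1c, the largest single rises of named genes in adult hepatocytes were those of the iron hormone hepcidin, Hamp (9.87 ± 0.93), the sulfotransferases Sult3a2 (9.02 ± 0.52) and Sult3a1 (8.81 ± 0.44), Cyp2b9 (8.80 ± 0.36) and the major urinary protein Mup3 (8.72 ± 0.40). Xist was at 10.20 in adult hepatocytes, against 4.41 in embryonic stem cells and 3.95 in hepatocyte-like cells. Differences of adult hepatocytes from both cultured kinds may therefore include some that go with sex, which was not tested. Sult3a1, Sult3a2, Mup3 and Serpina1c belong to families of near-identical copies, so that their probes can read more than 1 gene. Naive pluripotency genes fell in 25 of 28 (adjusted p = 1.61e-16), with Tdgf1 at -7.54 ± 0.53, Nanog at -7.22 ± 0.40, Nr0b1 at -6.88 ± 0.18 and Fbxo15 at -6.64 ± 0.19. Cell division genes fell in 21 of 21 (adjusted p = 4.52e-14, and adjusted p = 0.161 with an estimated correlation), Top2a by 5.48 ± 0.40 and Ccna2 fell by 5.33 ± 0.30. Genes of the p53 and DNA damage response fell in 13 of 19 with 0 rising (adjusted p = 1.58e-07), the death receptor Tnfrsf10b by 5.04 ± 0.20 and the cell cycle inhibitor Cdkn1a fell by 4.96 ± 0.32. Primed epiblast genes fell in 4 of 11 (adjusted p = 0.0178, and adjusted p = 0.155 with an estimated correlation), led by Dnmt3b (-3.42 ± 0.41), and were not called with dim genes left out (adjusted p = 0.0708).

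Genes of immune recognition did not all move 1 way in adult hepatocytes. In the MHC class I pathway 10 of 17 genes rose and 0 fell (adjusted p = 9.14e-06), Erap1 by 4.50 ± 0.32, H2-K1 by 3.41 ± 0.29, B2m by 3.07 ± 0.23 and H2-T23 by 2.57 ± 0.17. Inhibitory ligands of natural killer cells rose in 7 of 12 and fell in 2 (adjusted p = 0.00488, and adjusted p = 0.220 with an estimated correlation), with Clec2d, the ligand of the inhibitory receptor NKR-P1B, at 7.01 ± 0.23, Ceacam1 at 4.86 ± 0.29, Lgals9 at 4.47 ± 0.28 and Cd47 at 4.27 ± 0.15. Of 16 other activating or adhesion ligands 2 rose and 6 fell (adjusted p = 0.397), with Cd24a at -3.48 ± 0.35 and Ncam1 at -2.44 ± 0.23. Interferon-stimulated genes rose in 11 of 21 and fell in 1 (adjusted p = 1.72e-04, and adjusted p = 0.155 with an estimated correlation), led by the immunity-related GTPases Iigp1 (6.24 ± 0.34) and Igtp (3.97 ± 0.28). Markers of other liver cells were present in the adult samples beside these gains. Endothelial genes rose in 12 of 14 (adjusted p = 1.24e-07, and adjusted p = 0.0608 with an estimated correlation), with Ptprb at an adult mean of 9.15, Fcgr2b at 8.96 and Dnase1l3 at 8.89. Kupffer cell and macrophage genes rose in 12 of 16 (adjusted p = 5.58e-06), with Vsig4 at an adult mean of 7.35 and Csf1r at 7.24, while Cd68 fell by 2.46 ± 0.27. Stellate and fibroblast genes rose in 5 of 20 and fell in 2 (adjusted p = 0.0586, and adjusted p = 0.649 with an estimated correlation), with Dcn (5.16 ± 0.42) and the retinol esterifying enzyme Lrat (3.57 ± 0.21) among the higher. That list was called without hepatocyte-like replicate 1, 2 or 3 (adjusted p = 0.0316, 0.0478 and 0.0244) and with only these groups in the fit (adjusted p = 0.0115). It was also called with quantile normalization again, centring on the median and cyclic loess (adjusted p = 0.0422, 0.0303 and 0.0376), with a gene's clusters averaged (adjusted p = 0.0465), with array weights (adjusted p = 0.0484) and with the replicate number as a block (adjusted p = 0.0360).

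In this comparison 13 of 28 lists were called, 8 of them with an estimated correlation, and the counts adjusted over the list alone were the same for all 28. Cyclic loess, another between-array scaling, moved the share of called genes that were higher in adult hepatocytes from 41.5% to 52.0%.

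The third comparison set hepatocyte-like cells (n = 3) against adult hepatocytes (n = 3) and asks how far the differentiated cells were from mature ones. All 30 plasma protein genes were lower in hepatocyte-like cells (adjusted p = 1.75e-30), including Ambp (-7.79 ± 0.19) and plasminogen, Plg (-7.43 ± 0.25). So were 30 of 31 cytochrome P450 and conjugation genes (adjusted p = 1.31e-33), 26 of 27 metabolic enzymes (adjusted p = 7.80e-29) and 18 of 21 hepatocyte transcription factors (adjusted p = 1.03e-15). The carboxylesterase Ces3a fell by 8.19 ± 0.16, the transporter Slco1b2 fell by 8.42 ± 0.33, the bile acid receptor Nr1h4 fell by 4.96 ± 0.17 and the lipid-sensing receptor Ppara fell by 4.78 ± 0.22. Fetal liver genes were higher in 14 of 19 and lower in 5 (adjusted p = 0.00139), with Mest at 5.55 ± 0.34, Cldn6 at 4.80 ± 0.27 and Igf2 at 4.74 ± 0.25, against -7.22 ± 0.56 for the plasma protein Ahsg. In total 5106 genes were called, 3083 higher and 2023 lower, but with cyclic loess 2411 were higher and 2360 lower.

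Among single genes the largest gains in hepatocyte-like cells over adult hepatocytes were Bex3 (7.16 ± 0.22), Ptgs2 (7.09 ± 0.28), Nrk (7.02 ± 0.23), the collagen lysyl hydroxylase Plod2 (6.53 ± 0.28), Anxa1 (6.37 ± 0.35) and the calcium-binding S100a6 (6.29 ± 0.40). The largest falls were Sult3a2 (-8.42 ± 0.55), Slco1b2, Mup3 (-8.39 ± 0.43), Cyp2c69 (-8.22 ± 0.27), Sult3a1 (-8.21 ± 0.47) and Ces3a. Cell division genes were higher in 21 of 21 (adjusted p = 6.37e-11, and adjusted p = 0.204 with an estimated correlation), Top2a by 4.47 ± 0.43 and Mki67 by 3.87 ± 0.52. Genes of the p53 and DNA damage response were higher in 15 of 19 with 0 lower (adjusted p = 1.67e-08), Tnfrsf10b by 5.90 ± 0.22, Cdkn1a by 5.52 ± 0.35 and Eda2r by 4.81 ± 0.19. Stellate and fibroblast genes were higher in 13 of 20 and lower in 4 (adjusted p = 5.25e-04, and adjusted p = 0.306 with an estimated correlation), with Postn at 5.89 ± 0.41 and Acta2 at 5.76 ± 0.26. Extraembryonic endoderm genes were higher in 12 of 18 and lower in 3 (adjusted p = 3.89e-04, and adjusted p = 0.0513 with an estimated correlation), with Lamb1 at 4.85 ± 0.22. Cholangiocyte genes were higher in 5 of 8 (adjusted p = 0.00139, and adjusted p = 0.146 with an estimated correlation), with Epcam at 4.40 ± 0.25.

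Genes of MHC class I were lower in hepatocyte-like cells than in adult hepatocytes. In that pathway 10 of 17 fell and 0 rose (adjusted p = 3.75e-06), Erap1 by 3.31 ± 0.34, H2-T23 by 2.54 ± 0.19, H2-K1 fell by 2.07 ± 0.31 and B2m fell by 1.42 ± 0.24. Of 12 inhibitory ligands 4 fell and 2 rose, with Clec2d at -6.52 ± 0.25, Ceacam1 at -6.04 ± 0.31, Lgals9 at -3.12 ± 0.30 and Cd200 at 1.82 ± 0.35. That list was called at adjusted p = 0.0395, but not with the correlation estimated (adjusted p = 0.306 with an estimated correlation), without hepatocyte-like replicate 1 (adjusted p = 0.0549) or without replicate 3 (adjusted p = 0.0640, in a range of 0.0169 to 0.0640 over the alternatives that keep the preset correlation). Of 16 other activating or adhesion ligands 5 rose and 1 fell (adjusted p = 0.174), with Cd24a at 5.91 ± 0.37, Ncam1 at 4.64 ± 0.24, the DNAM-1 ligand Pvr at 2.67 ± 0.32 and Nectin3 at -1.54 ± 0.21. Interferon-stimulated genes fell in 9 of 21 and rose in 2 (adjusted p = 5.13e-04, and adjusted p = 0.168 with an estimated correlation), Iigp1 by 5.93 ± 0.36. Of 18 killing pathway and granzyme inhibitor genes 6 rose and 2 fell (adjusted p = 0.177), the latter Serpina3n (-2.37 ± 0.24) and the caspase inhibitor Cflar (-2.12 ± 0.21). Markers of other liver cells fell too, endothelial genes in 11 of 14 (adjusted p = 4.99e-10) and Kupffer cell genes in 13 of 16 (adjusted p = 1.27e-06), with Ptprb at -3.80 ± 0.26 and Vsig4 at -3.95 ± 0.26.

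Here 16 of 28 lists were called, 9 of them with an estimated correlation, and the call of the primed epiblast list (adjusted p = 0.0415, and adjusted p = 0.204 with an estimated correlation) was lost without adult replicate 1, without adult replicate 3 or without hepatocyte-like replicate 3 (adjusted p = 0.0667, 0.0560 and 0.0925). It was also lost with dim genes left out, with array weights and with only these groups in the fit (adjusted p = 0.173, 0.0561 and 0.0518), and the lowest adjusted p of an alternative that keeps the preset correlation was 0.0169. Counts adjusted over the list alone differed for stellate and fibroblast genes (14 higher) and cardiac and muscle genes (1 higher, against 2 over all genes).

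The last comparison asked how much of the adult difference the hepatocyte-like cells shared. Of 1267 genes at least 4-fold higher in adult hepatocytes than in embryonic stem cells, 345 (27.2%) were also called higher in hepatocyte-like cells and 47 (3.71%) were called lower. Of 1234 genes at least 4-fold lower in adult hepatocytes, 705 (57.1%) were also called lower in hepatocyte-like cells and 49 (3.97%) were called higher. Both sets were chosen by the difference alone and are not limited to hepatocyte genes. The shares therefore do not measure a gain of hepatocyte functions, whose lists changed little as given above. With genes at least 2-fold apart in place of 4-fold the shares were 26.3% of the higher and 35.4% of the lower genes. Independent lists of these sizes would share 8.61% and 7.35%, taken over all 22180 genes. With dim genes left out, 1887 higher and 1600 lower genes were called among 14832, so the percent expected among brighter genes is higher. The same stem cell arrays serve both sides. In 100 simulations unchanged hepatocyte-like cells were drawn around the observed stem cell means, which gave a mean of 0.00158% (at most 0.0789%) and 0%. Such draws leave out the error of the stem cell arrays that both sides share, so they do not measure its part. With the stem cell arrays divided between the comparisons, 2 in each over 6 divisions, the shares averaged 25.5% (25.2 to 26.1) and 52.7% (48.2 to 54.9), against 8.23% and 7.29% for independent lists.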

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

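The tests of the adult transcripts in hepatocyte-like replicate 3 were chosen only after the result was seen.

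Among the 4 arrays of embryonic stem cells, 9 of 163 values held an array far from the others, by the ratio of its gap to the whole range (Dixon's 95% critical value). Chance flags about 1 in 20 groups, and 9 of 163 is near that. The ratio was 0.991 for Adh1 (replicate 1 at 6.45, the next at 7.50), 0.983 for Anxa1 (replicate 3 at 7.58, the next at 6.40), 0.927 for Nr0b1 (replicate 3 at 10.99, the next at 10.83) and 0.902 for Nrk (replicate 4 at 3.40, the next at 4.15). It was 0.882 for Egr1 (replicate 3 at 6.25, the next at 4.95), 0.861 for Ces3a (replicate 3 at 3.86, the next at 3.99), 0.855 for Cd68 (replicate 1 at 9.17, the next at 9.62) and 0.835 for Iigp1 (replicate 2 at 3.33, the next at 3.89). For the mean of the mesendoderm and definitive endoderm list it was 0.900 (replicate 4 at 6.05, the other end at 5.99).

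Signals stood in data outside the comparisons. A transcript cluster shared by Raet1 genes, which encode NKG2D ligands, was higher in hepatocyte-like cells than in embryonic stem cells by 1.19 ± 0.22 (adjusted p = 0.00255), and its members cannot be named singly. It was not called in hepatocyte-like cells against adult hepatocytes (0.74 ± 0.23, adjusted p = 0.0380) or in adult hepatocytes against embryonic stem cells (0.45 ± 0.22, adjusted p = 0.161). Among 16010 clusters with no gene symbol, 1226 were called between hepatocyte-like and embryonic stem cells, 1785 between adult hepatocytes and embryonic stem cells and 1407 between hepatocyte-like cells and adult hepatocytes.

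Hepatocyte-like replicate 3 carried the most abundant adult hepatocyte transcripts at higher levels than replicates 1 and 2, but was highest of the 3 in only 31 of 125 genes at the floor in stem cells and at adult levels of 8 to 9, and it also differed in Nanog (7.12 against 5.08 and 5.09), Tdgf1 and Esx1, which adult RNA would not bring. A stronger hepatocyte programme across the cells of that culture was taken to raise the hepatocyte transcription factors. These had a median of -0.21 in replicate 3 relative to replicates 1 and 2 (quartiles -0.59 and 0.06). Of 21 factors 12 were lower there than in both others and 5 were higher. The factors as a set were thus not raised. This covers their transcripts alone and does not exclude a stronger programme in other genes. RNA of adult hepatocytes at a trace share, from outside the culture, stays open: of 34 abundant adult genes at the floor in stem cells 30 were highest in replicate 3 among the hepatocyte-like arrays, where an equal share is 11.3, which falls short of the bound set for that explanation. A small share of adult-like cells cannot be told apart from such RNA, since both would give the same share: its median was 0.576% of the adult level for these 34 genes (0.297% at adult levels of 11 to 12), and 0.529% (quartiles 0.433 and 0.821; 0.288% at 11 to 12) for the 27 that were also at the floor in replicates 1 and 2, a choice that favours replicate 3. Hamp at 16.6%, Alb at 15.8% and Serpina1c at 3.75% lay far above it. So did 8 genes at adult levels of 8.01 to 10.18 (4.35% to 13.2%). These 8 were picked among genes also at the floor in replicates 1 and 2, a choice that again favours replicate 3. Saturation of the adult signal is no reason for those 8. It is an uncertain one for Hamp, since Cyp2e1 at the same adult level (13.12 and 13.11) read 0.883%. Without that choice, 443 genes were at the floor in stem cells. Among them shares over 4.10% were about as frequent in replicates 1 and 2 (64 and 73) as in replicate 3 (74).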

How the results depend on the processing

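The subtraction of the adult share from hepatocyte-like replicate 3 was chosen after the data were seen. No called gene or list named here turned its direction, but the balance of called genes did. In hepatocyte-like against embryonic stem cells 48.0% were higher with each array centred on its median, against 53.9%, and in adult hepatocytes against embryonic stem cells 52.0% with cyclic loess, against 41.5%. Of 3757 values of named genes under the alternatives 3741 kept their side of the threshold, 12 lost a call and 4 gained one, and of 1839 values of lists 1768 kept it, 34 lost and 37 gained a call. Among the NKG2D ligands measured singly, the number called in hepatocyte-like against embryonic stem cells ranged from 0 to 1 when 1 array was left out. It was 0 without hepatocyte-like replicate 1 or 3, because H60b was no longer called. The cluster shared by Raet1 genes was not tested with arrays left out. With the correlation estimated camera called 3, 8 and 9 lists instead of 9, 13 and 16, in the order hepatocyte-like against embryonic stem cells, adult hepatocytes against embryonic stem cells and hepatocyte-like cells against adult hepatocytes. Fry, which does not compare a list with other genes, called 16, 24 and 23. An adjusted p alone gave 6390, 9205 and 8003 genes and a test against a log2 difference of 1 (treat) 1189, 3378 and 2529, since these loosen or tighten the threshold itself. With genes at least 2-fold lower in adult hepatocytes taken in place of 4-fold, 35.4% were also lower in hepatocyte-like cells, and the cause was not tested. The replicate number as a block gave 3518, 5926 and 5103 genes. Leaving out single arrays gave 3349 to 3719, 5797 to 6010 and 4933 to 5272 genes. Cyclic loess changed the share of called genes that were higher from 53.9%, 41.5% and 60.4% to 56.4%, 52.0% and 50.5%. Subtracting 0.529% of the adult level from hepatocyte-like replicate 3 gave 3537 genes for hepatocyte-like against embryonic stem cells, of which 3526 are among the 3540, and ended the call of the plasma protein list there (adjusted p = 0.188). Signal over background could not be measured, and genes near the floor of the arrays give no bound on low transcripts.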

Other observations

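In this part the tests of X-linked and Y-linked genes, of Xist and of splits with an estimated correlation, and the choice of Rian and Meg3, came only after the results were seen.

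Rian, a noncoding RNA of the imprinted Dlk1-Dio3 locus that is expressed from the maternal copy, was high in both cultured kinds and at the floor in adult hepatocytes. Its mean log2 level was 10.05 ± 0.41 (SD, n = 3) in hepatocyte-like cells, 8.69 ± 0.13 (n = 4) in embryonic stem cells and 3.83 ± 0.36 (n = 3) in adult hepatocytes. It rose by 1.36 ± 0.22 (SE) from embryonic stem cells to hepatocyte-like cells (adjusted p = 3.90e-04). Meg3, another transcript of that locus, read 5.35, 5.16 and 5.31, and its difference between hepatocyte-like and embryonic stem cells was 0.19 ± 0.21 (adjusted p = 0.573). Its means lay below 5.5, the level taken as the floor here, so they give no bound on a change of Meg3. Genes of other lists also moved between adult hepatocytes and embryonic stem cells. The early response genes Zfp36 (4.15 ± 0.27), Egr1 (3.41 ± 0.50), Jun (3.02 ± 0.27) and the heat shock gene Hspb1 (-4.16 ± 0.29) changed, while that list was not called (adjusted p = 0.245). The neuronal gene Stmn2 fell by 6.14 ± 0.52 and Tubb3 fell by 2.86 ± 0.42 in a list not called (adjusted p = 0.205).

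Xist, the RNA that silences 1 X chromosome in female cells, was at 10.20 ± 0.16 (SD, n = 3) in adult hepatocytes, 3.95 in hepatocyte-like cells and 4.41 in embryonic stem cells, and no Y-linked gene was above 3.73 on any array of cultured cells. The sex of the animals and of the stem cell line is not given in the sources used here. A pair of active X chromosomes in the stem cells would put X-linked genes above autosomal ones relative to adult hepatocytes, by at most about 1. The 108 X-linked genes lay 0.13 above the autosomes (medians 0.39 and 0.25, with autosomes between 0.01 and 0.53). That argues against a rise near 1, but with such a spread of the autosomes a smaller one is not excluded. A cell line with a single X chromosome and no Y, and Y-linked probes that do not detect their genes, cannot be told apart, since no array here is known to carry a Y chromosome and the adult arrays read at most 3.87.

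Of 20 stellate and fibroblast genes 14 rose in hepatocyte-like cells. Feeder or other fibroblasts of female or mixed-sex origin from outside the line would bring Xist, yet Xist differed by -0.46 between hepatocyte-like and embryonic stem cells (95% interval -0.83 to -0.09), far below its level in adult hepatocytes. Fibroblasts of male origin and mesenchymal cells arising from the line itself stay open, and no test here separates them.

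Other splits of the same arrays were counted. Of 35 splits of the 7 arrays of hepatocyte-like and embryonic stem cells, 1, the real one, gave as many called genes (3540, highest other 4). That is the smallest share that 35 splits can give. The other splits mix the 2 kinds, which puts the difference between them into the spread. Their low counts therefore do not show what unchanged arrays would give. Called NKG2D ligands (real 1, highest other 0), adult genes also higher in hepatocyte-like cells (27.2%, highest other 0%) and stem cell genes also lower (57.1%, highest other 0%) were matched by 1 split too, the real one. With at most 4 genes called in the other splits this follows from the count of genes and is no evidence of its own. For gene lists, 9 of 35 splits gave as many as the real 9 (highest other 13), so chance is not excluded for that count. With an estimated correlation 1 split did, the real one (real 3, highest other 0), again the smallest share possible and with the same limit. Of 35 splits of adult hepatocytes and embryonic stem cells, 1 gave as many genes (real 5893, highest other 2) and 1 as many lists with an estimated correlation (real 8, highest other 0). The same limit holds for these. The ligands (real 1, highest other 0, 1 split) again follow from the count of genes. There 6 splits gave as many lists with the preset correlation (real 13, highest other 14), so chance is not excluded for that count. For hepatocyte-like cells against adult hepatocytes the 10 splits are too few for a share under 0.05: genes were 5106 against at most 0, ligands 2 against 0, lists 16 against 16 (2 splits) and lists with an estimated correlation 9 against 0.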
